A study of Homo sapiens with 9 samples.

How the data were processed

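RNA of FaDu cells, an established line of human hypopharyngeal squamous carcinoma, was measured by bulk RNA sequencing in 9 libraries. Per the labels, 3 libraries came from control cells, 3 from cells with AMIGO2 knocked down and 3 from cells with AMIGO2 knocked down and CAPN2 overexpressed, each set holding 3 biological replicates. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit, which does not mark strand.

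The authors deposited 1 table of raw counts of reads per gene for 58735 genes, with whole numbers that were not normalised. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were named, without their roles, together with the genome build hg19. The coordinates in the deposited table were those of the GENCODE v29 annotation on GRCh38 for 58735 of 58735 gene identifiers, so positions are given on GRCh38. The strand setting, the treatment of reads matching several places and the treatment of reads in overlapping genes are not given in the sources used here. Reads of a gene and of an overlapping gene on the other strand could therefore not be told apart. Of the 277 genes named by the rule given further on, 21 shared exon sequence with another tested gene that had at least 10% of their level, and CCND1, DDIT3, FEN1, HSPE1, SLC6A9 and TYMS were among them. Deposited counts of genes with near-identical copies, such as HSPA6, HSPA1A, the keratin 6 genes and the ribosomal protein genes, may be split between copies by the counting and are uncertain to that extent.

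Totals ran from 15158607 to 19737562 counts per library. At these depths 3 counts corresponded to between 0.152 and 0.198 CPM. These limits cover counting error only.

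Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough counts were kept with edgeR's filterByExpr (at least 10 counts, by group), which left 16812 genes, and libraries were scaled with trimmed mean of M values (TMM) factors. A quasi-likelihood model with 1 term per group was fitted to all 9 libraries with robust dispersion, leaving 6 residual degrees of freedom before moderation. The 3 contrasts were tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05. Standard errors (SE) were taken as the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD. No adjusted p rests on samples other than these cultures of 1 cell line.

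The gene lists, the rule for named genes and all alternatives were fixed before the data were examined, with the following exceptions. The correction for GC content and length, the comparison without shared libraries and 2 further stress response lists under other observations came later. The lists fixed beforehand numbered 33 with 904 genes. Of these genes 892 were found in the table, 2 of them under an older symbol. The 31 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast. Camera with an estimated correlation and fry were alternatives. Members past the threshold were counted over all genes tested and also adjusted over the list alone.

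The genes named were chosen by that rule. AMIGO2 and CAPN2 were always named. For each contrast the rule took the 10 largest rises and the 10 largest falls among protein-coding genes called changed, without overlap of the groups' libraries and with a mean of at least 5 CPM. For each list it took up to 2 risen and 2 fallen members with the lowest adjusted p. For genes that moved back, at the same minimum of 5 CPM, it took the 5 in each direction with the largest smaller change. Genes named outside this rule are said to be so, and some genes that it named are not reported here.

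Genes that moved back were those called in the libraries labelled knockdown against control and called in the opposite direction in the libraries labelled knockdown plus CAPN2 against the libraries labelled knockdown. Both contrasts use the libraries labelled knockdown, so 20 data sets without any effect were simulated and the numbers expected of independent lists were computed. The comparison was also made with no library in both contrasts, over the same genes, and with 20 data sets simulated without effect. Each library labelled knockdown was in turn alone in one contrast, with the other 2 in the second. A library alone has no spread of its own, so the spread came from the other libraries.

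The same steps were tested on simulated counts with 200 genes changed by known folds. For the contrast of knockdown with control, 53.7%, 74.6% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold were called, and 8.18% of calls were unchanged genes, among 16418 genes. For knockdown plus CAPN2 against knockdown these shares were 47.8%, 79.1% and 97.0%, with 7.45% of calls wrong among 16427 genes. For knockdown plus CAPN2 against control they were 61.2%, 80.6% and 90.9%, with 4.32% of calls wrong among 16441 genes.

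The alternatives were other scaling factors (median of ratios, upper quartile), DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, fits to the compared groups alone, a block on the replicate number, and leaving out each library. A requirement of a 2-fold change and a restriction to protein-coding genes were also tried for the counts of changed genes. A correction of each library for smooth trends over GC content and gene length, fitted with mgcv 1.9.3, was added after the data were seen. Figures were drawn with matplotlib 3.10.9.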

Results

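Gene expression was measured in 9 cultures of FaDu, a squamous carcinoma line of the hypopharynx, in 3 groups of 3. By their labels, the groups compare knockdown of AMIGO2 with control, and overexpression of CAPN2 on top of it with the knockdown alone. AMIGO2 encodes a cell-surface protein with leucine-rich repeats, and CAPN2 the large subunit of the calcium-dependent protease calpain-2. The control libraries held 16627509 ± 1324301 counts (SD, n = 3), those labelled knockdown 18020087 ± 1531302 and those labelled knockdown plus CAPN2 16033075 ± 413378. Library totals lay between 15158607 and 19737562 counts.

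No fall of AMIGO2 against control was called in either set of libraries labelled with its knockdown. AMIGO2 (ENSG00000139211, GRCh38 chromosome 12, 47075707 to 47079951, minus strand) stood at 27.6 ± 1.73 CPM in the control libraries (SD, n = 3) and at 27.7 ± 3.41 CPM in the libraries labelled knockdown. The log2 fold change was 0.006 ± 0.115 (SE) with a 95% interval from -0.235 to 0.248, and edgeR's adjusted p was 0.971. In the libraries labelled knockdown plus CAPN2 it stood higher, at 39.0 ± 3.79 CPM, 1.41-fold above control (log2 0.50 ± 0.114, adjusted p = 0.00106) and 1.41-fold above the libraries labelled knockdown (log2 0.49 ± 0.114, adjusted p = 0.0014). Single libraries held 29.5, 26.1 and 27.2 CPM in control, 24.5, 31.3 and 27.3 CPM under the knockdown label, and 42.8, 35.3 and 38.8 CPM under the label of knockdown plus CAPN2. The 5′ end of AMIGO2 overlaps PCED1B on the plus strand, which had 511 counts in all 9 libraries together.

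CAPN2 (ENSG00000162909, GRCh38 chromosome 1, 223701593 to 223776018, plus strand) overlaps no other annotated gene. It stood at 462 ± 13.9 CPM in control, 418 ± 20.3 CPM in the libraries labelled knockdown and 499 ± 1.29 CPM in those labelled knockdown plus CAPN2 (SD, n = 3). The libraries labelled knockdown plus CAPN2 exceeded those labelled knockdown 1.19-fold (log2 0.26 ± 0.079, edgeR adjusted p = 0.012). Against control the log2 fold change was 0.11 ± 0.079 (adjusted p = 0.254, 95% interval -0.057 to 0.275), and between the libraries labelled knockdown and control it was -0.15 ± 0.079 (adjusted p = 0.166). The former passed with upper-quartile factors (log2 0.21, adjusted p = 0.0278) and in the fit to the compared groups alone (0.12, adjusted p = 0.0389), and turned to -0.06 after the GC and length correction (adjusted p = 0.461). The latter passed after that correction (-0.22, adjusted p = 0.00938). The 1.19-fold difference did not pass without a filter on low counts (adjusted p = 0.0871) or without the first library labelled knockdown plus CAPN2 (adjusted p = 0.0601), over a range of 0.00267 to 0.0871 across 18 alternatives. No direction given from here on rests on a measured knockdown or overexpression. Each is a difference between sets of libraries named by their labels.

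**Figure D1:**
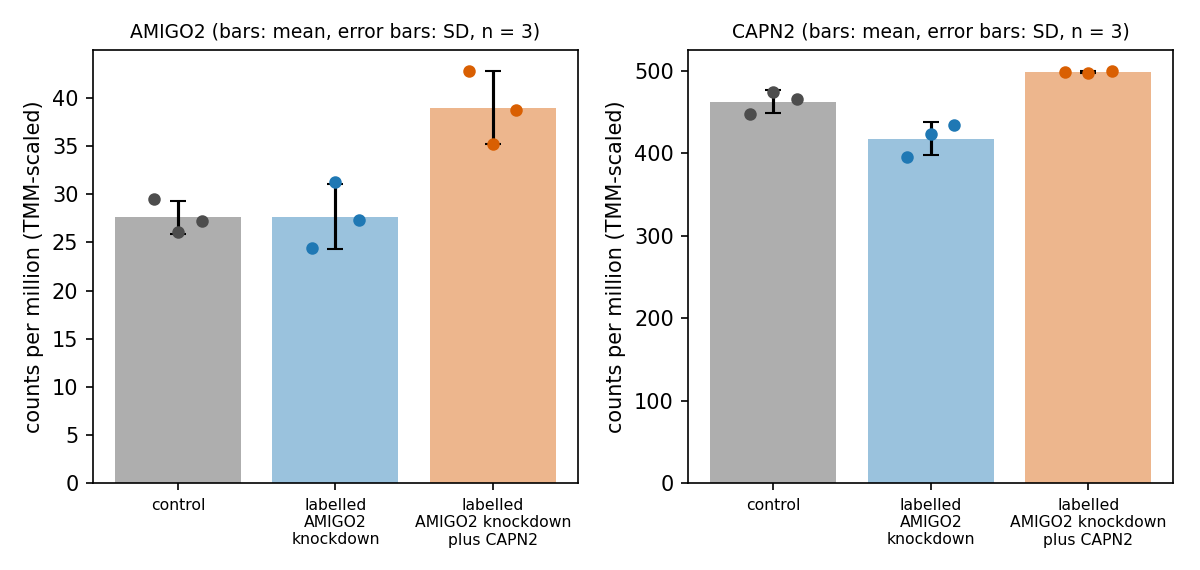
AMIGO2 (left) and CAPN2 (right) in TMM-scaled CPM for each library, with bars for the group mean and error bars for the SD of 3 libraries. AMIGO2 was 27.6 in control and 27.7 under the knockdown label, and CAPN2 lay between 418 and 499 in all 3 groups.

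On the first 2 principal components, which held 50.3% and 23.3% of the variance, the 3 sets did not mix. Correlations of log2 CPM ran from 0.984 to 0.990 within groups and from 0.945 to 0.976 between groups. The libraries labelled knockdown were the least alike. Their mean chi-square per gene between libraries was 21.2 to 21.7 (genes with at least 20 counts in the pair). This measure was 2.69 to 5.06 within control, 3.02 to 7.61 within the libraries labelled knockdown plus CAPN2, and 29.1 to 139 between groups. The model took 1 spread per gene from all 9 libraries. SE and p-values may therefore be too small in the 2 contrasts with the libraries labelled knockdown. They may be too large in the contrast of knockdown plus CAPN2 with control. Mitochondrial ribosomal RNA took 0.557 ± 0.0233% of counts in control, 0.954 ± 0.113% under the knockdown label and 1.04 ± 0.019% under the label of knockdown plus CAPN2 (SD, n = 3), and long non-coding RNA took 0.979 ± 0.0212%, 1.11 ± 0.0509% and 1.55 ± 0.044%.

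In the libraries labelled knockdown, genes for secreted proteases stood above control, while mitotic genes stood below it. MMP3, which encodes a matrix metalloproteinase, rose 26.2-fold (log2 4.71 ± 0.188 SE) from 1.68 ± 0.211 to 44.4 ± 8.31 CPM (SD, n = 3). The lysyl oxidase gene LOX rose 9.87-fold from 1.74 ± 0.284 to 17.3 ± 1.18 CPM. KRT5, a keratin of basal squamous epithelium, fell 3.68-fold (log2 -1.88 ± 0.106) from 4437 ± 133 to 1207 ± 180 CPM. LMNB1, which encodes lamin B1 of the nuclear lamina, fell 3.48-fold from 376 ± 9.01 to 108 ± 10.9 CPM. Exons of SLC6A9, KIF20A and CAST, named further on, overlap those of CCDC24, CDC23 and ERAP1 on the other strand, so their values are uncertain.

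The other largest rises against control were those of SYTL2 (log2 4.28 ± 0.235), DIO2 (4.21 ± 0.203), the cytokine gene IL24 (3.69 ± 0.159), STC1 (3.32 ± 0.151), ADAM12 (3.32 ± 0.230), MMP12 (3.18 ± 0.137), STMN3 (3.07 ± 0.168) and MMP10 (2.95 ± 0.104). The other largest falls were those of NUPR1 (log2 -2.53 ± 0.358, at 0.598 CPM in the libraries labelled knockdown), the glycine transporter gene SLC6A9 (-2.13 ± 0.151), KRT15 (-2.01 ± 0.113), HRNR (3.47-fold lower), XXYLT1 (-1.79 ± 0.137), MBNL3 (-1.69 ± 0.151), DKK3 (-1.64 ± 0.139) and SH3PXD2B (-1.61 ± 0.202). In all 3 contrasts such rankings cover only protein-coding genes without overlap of the groups' libraries and with a mean of at least 5 CPM over all 9 libraries. Adjusted p of these 20 genes in edgeR ran from 4.86e-13 for MMP10 to 2.57e-05 for NUPR1. Of 16812 genes tested, 5812 were called changed, 2696 higher and 3116 lower, with 718 higher and 393 lower by at least 2-fold. The larger direction depended on the scaling, with 46.4% of calls higher here and 53.9% with upper-quartile factors. The libraries of the 2 groups did not overlap for 44.7% of genes, against 10% by chance.

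Of the 28 tested members of the list of matrix and secreted proteases, 19 rose, 0 fell and 9 did not pass (adjusted over the list alone, 19 rose and 1 fell). The median log2 fold change was 0.81 and camera's adjusted p was 7.07e-28, and 0.0136 with an estimated correlation. Of the 15 lists called in this contrast, 10 held with an estimated correlation, at camera adjusted p from 0.0136 to 0.0448. MMP1, an interstitial collagenase, rose 6.88-fold from 64.3 ± 2.00 to 442 ± 50.2 CPM. Among 20 mesenchymal transition genes 12 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 6.53e-13), with LOXL2 up 2.93-fold and PDPN down 1.84-fold. Integrin genes rose in 9 of 14 cases and fell in 2 (9 and 3 adjusted over the list alone, camera adjusted p = 0.000304), among them ITGB1, up 2.04-fold from 360 ± 11.7 to 734 ± 5.73 CPM, and ITGB4, down 1.45-fold.

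Inflammatory, signalling and hypoxia lists were higher as well. Of 30 NF-kB and cytokine genes 17 rose and 5 fell (18 and 6 adjusted over the list alone, camera adjusted p = 1.44e-07), among them the neutrophil chemokines CXCL8 (3.28-fold) and CXCL1 (3.13-fold). TGF-beta response genes rose in 10 of 23 cases and fell in 1, counts that were also 10 and 1 adjusted over the list alone (camera adjusted p = 1.69e-05), with TGFB2 up 6.24-fold. Feedback genes of EGFR and MAPK signalling rose in 15 of 30 cases and fell in 5, as they did adjusted over the list alone (camera adjusted p = 6.43e-06), with DUSP4 up 5.09-fold. YAP and TAZ targets rose in 10 of 24 cases and fell in 7, likewise adjusted over the list alone (camera adjusted p = 6.43e-06), with the coagulation factor gene F3 up 3.51-fold. The median of this list was only 0.04 against a mean of 0.42, and it ran from -0.01 to 0.11 over 13 alternatives. FOXO targets and PI3K feedback genes, tested as 1 list, rose in 12 of 26 cases and fell in 3 (camera adjusted p = 8.1e-05). Adjusted over the list alone, 13 rose and 3 fell. That call was lost at camera adjusted p = 0.0878 with an estimated correlation. Hypoxia and glycolysis genes rose in 16 of 32 cases and fell in 5 (16 and 6 adjusted over the list alone, camera adjusted p = 0.000149), a call lost at adjusted p = 0.224 with an estimated correlation.

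Mitotic genes fell as a group in the libraries labelled knockdown. Of 34 genes of G2 and mitosis 29 fell and 0 rose (30 and 0 adjusted over the list alone), with a median log2 fold change of -0.59. Camera's adjusted p was 7.38e-18, and 0.0255 with an estimated correlation. KIF20A, a mitotic kinesin, fell 2.52-fold and the kinase gene PLK1 2.20-fold. Cholesterol and fatty acid synthesis genes fell in 20 of 31 cases and rose in 3, also adjusted over the list alone (camera adjusted p = 8.25e-05), with SCD down 1.89-fold. Wnt and Notch genes fell in 12 of 27 cases and rose in 4, also adjusted over the list alone (camera adjusted p = 0.00126), with HES2 down 7.83-fold. That call was lost after the GC and length correction (adjusted p = 0.0575, within 2.57e-05 to 0.0575 over 13 alternatives).

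Basal keratinocyte genes fell in 10 of 18 cases and rose in 4, also adjusted over the list alone (camera adjusted p = 0.00545), with KRT15 and KRT5 among those that fell. The call was lost at adjusted p = 0.279 with an estimated correlation, and at 0.0642 without the third library labelled knockdown, where the median log2 fold change was -0.36 instead of -0.46 (range of adjusted p 0.00146 to 0.279 over 13 alternatives). Cytosolic ribosomal protein genes fell in 16 of 74 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.0262, and adjusted p = 0.749 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 11 of 42 cases and rose in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 0.0255, and adjusted p = 0.68 with an estimated correlation). Neither of these 2 calls held without the second control library (adjusted p = 0.0923 and 0.0554), without the first library labelled knockdown (0.114 and 0.0595) or without the second (0.385 and 0.146). Over 13 alternatives their adjusted p ran from 1.83e-06 to 0.749 and from 0.000144 to 0.68.

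The remaining 16 of the 31 lists tested were not called. The unfolded protein and integrated stress response list divided, with 13 genes risen, 14 fallen and 4 not past the threshold of 31 (14 and 14 adjusted over the list alone, camera adjusted p = 0.489). HSPA5 and HSP90B1, chaperones of the endoplasmic reticulum, rose 2.67-fold and 2.53-fold. PHGDH, an enzyme of serine synthesis, and SESN2 fell 2.18-fold and 2.14-fold. In the calpain list 2 genes rose, 3 fell and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.407), with CAPN1 down 1.70-fold and CAST, which encodes the calpain inhibitor calpastatin, up 1.27-fold. S phase genes rose in 3 and fell in 12 of 33 cases (4 and 12 adjusted over the list alone, camera adjusted p = 0.274). In the squamous differentiation list 7 genes rose and 11 fell of 25, also adjusted over the list alone (camera adjusted p = 0.482), and its median of -0.05 and mean of 0.14 differed in sign. The list of AMIGO and related adhesion genes had a median of 0.11 and a mean of 0.08 but a test direction downward (camera adjusted p = 0.906). Markers of other cell types were few. Of 14 endothelial markers 5 were tested, of which CDH5 rose 2.91-fold to 43.2 ± 2.93 CPM and VWF fell 2.32-fold. Of 4 tested blood and immune markers 2 rose and 0 fell, and of 4 fibroblast markers 1 rose and 1 fell, too few for a test. The lists of mitochondrial messenger RNA and of replication histones, read as signs of RNA quality, were not called (camera adjusted p = 0.647 and 0.124). Of 13 replication histone genes 6 fell and 1 rose, with a median of -0.31 and an adjusted p of 0.00334 with fry.

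Fold changes in this contrast followed GC content across genes (Spearman's rho = -0.363 over 16802 genes, which are not independent replicates). The correction for GC content and length left 6195 genes called, of which 4633 were among the 5812. A trend of the same sign ran through the libraries labelled knockdown plus CAPN2 against control (rho = -0.287), where 7980 of 9468 calls were kept by the correction, and a weaker one against the libraries labelled knockdown (rho = -0.083).

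The addition labelled CAPN2 was compared with the libraries labelled knockdown. Genes of the unfolded protein and integrated stress response rose together and genes of DNA replication fell together. NUPR1, a stress-induced transcription regulator, rose 30.2-fold (log2 4.92 ± 0.309 SE) from 0.598 ± 0.479 to 17.6 ± 1.97 CPM (SD, n = 3). ALDH1L2, a mitochondrial enzyme of folate metabolism, rose by a log2 fold change of 3.46 ± 0.134 from 3.49 ± 0.338 to 38.5 ± 2.87 CPM. TXNIP, which encodes a thioredoxin-interacting protein that responds to glucose, fell 16.6-fold (log2 -4.05 ± 0.110) from 102 ± 5.18 to 6.14 ± 0.512 CPM. MMP10 fell (log2 -3.17 ± 0.106) from 163 ± 15.1 to 18.1 ± 1.49 CPM.

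Beyond these, LAMP3 (log2 3.33 ± 0.103), INHBE (3.30 ± 0.185), UNC5B (3.21 ± 0.089), SLC6A9 (3.19 ± 0.152), the sterol exporter gene ABCG1 (3.13 ± 0.149), RPS6KA2 (3.06 ± 0.204), the centromere kinesin gene CENPE (2.84 ± 0.145) and the amino acid transporter gene SLC1A4 (2.82 ± 0.106) had the largest rises. HSPA6 (-4.56 ± 0.203, a gene with a near-identical copy and so uncertain), SYTL2 (-3.63 ± 0.218), MMP3 (-3.46 ± 0.166), CPA4 (-3.08 ± 0.165), NT5E (-3.05 ± 0.139), CST6 (-2.96 ± 0.170), DIO2 (-2.90 ± 0.177) and MMP1 (-2.83 ± 0.096) had the largest falls. In edgeR these 20 genes had adjusted p from 5.82e-15 for TXNIP to 7.84e-10 for RPS6KA2. The test called 8278 of 16812 genes, 3981 higher and 4297 lower, with 1447 higher and 824 lower by at least 2-fold. Higher calls made up 48.1%, against 54.3% with upper-quartile factors and 44.8% in DESeq2. Libraries did not overlap for 54.0% of genes, against 10% by chance.

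All 31 genes of the unfolded protein and integrated stress response list rose, also adjusted over the list alone, with a median log2 fold change of 1.54 (camera adjusted p = 3.45e-53, and adjusted p = 0.00115 with an estimated correlation). DDIT3, which encodes the stress-induced factor CHOP, rose 6.77-fold from 10.8 ± 2.00 to 73.2 ± 5.13 CPM, and its exons overlap those of MARS on the other strand. HERPUD1, a gene of protein degradation at the endoplasmic reticulum, rose 4.01-fold to 375 ± 13.4 CPM. All 33 tested S phase genes fell, also adjusted over the list alone, with a median of -1.35 (camera adjusted p = 7.71e-43, and adjusted p = 0.00115 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, fell 3.31-fold from 188 ± 21.5 to 56.7 ± 3.16 CPM, and FEN1, whose exons overlap those of TMEM258 and FADS2, fell 3.74-fold. These were the only 2 of 14 called lists that held with an estimated correlation.

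The other 12 calls rested on the preset correlation of camera. Protease genes fell in 16 of 28 cases and rose in 7 (16 and 8 adjusted over the list alone, median -0.75, camera adjusted p = 1.04e-08, and adjusted p = 0.0739 with an estimated correlation). Heat shock genes fell in 12 of 14 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 1.47e-10, and adjusted p = 0.0628 with an estimated correlation), with HSPA8 down 2.55-fold. Nuclear oxidative phosphorylation genes fell in 38 of 42 cases and rose in 0 (39 and 0 adjusted over the list alone, camera adjusted p = 1.43e-09, and adjusted p = 0.311 with an estimated correlation), with ATP5MC3 down 2.71-fold. Of the G2 and mitosis genes 24 fell and 4 rose (26 and 4 adjusted over the list alone, camera adjusted p = 0.000167, and adjusted p = 0.213 with an estimated correlation). Those that rose included CENPE, 7.16-fold, and CENPF, 4.24-fold, which encode large kinetochore proteins, while the survivin gene BIRC5 fell 2.43-fold. Cholesterol synthesis genes fell in 19 and rose in 6 of 31 cases (19 and 7 adjusted over the list alone, camera adjusted p = 0.00344, and adjusted p = 0.0851 with an estimated correlation), with HMGCS1 down 2.23-fold and SREBF1 up 1.72-fold.

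NF-kB and cytokine genes rose in 15 and fell in 6 of 30 cases (15 and 7 adjusted over the list alone, camera adjusted p = 0.000302, and adjusted p = 0.213 with an estimated correlation), with the siderophore-binding gene LCN2 up 3.30-fold and CXCL1 down 1.58-fold. Interferon response genes rose in 18 and fell in 11 of 39 cases (18 and 12 adjusted over the list alone, camera adjusted p = 0.0244, and adjusted p = 0.302 with an estimated correlation), with STAT2 up 2.14-fold. TGF-beta response genes fell in 11 and rose in 5 of 23 cases, also adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.213 with an estimated correlation), with CTGF down 4.14-fold. YAP and TAZ targets fell in 13 and rose in 5 of 24 cases (14 and 6 adjusted over the list alone, camera adjusted p = 0.0138, and adjusted p = 0.203 with an estimated correlation), with CYR61 down 3.34-fold. Mesenchymal genes fell in 10 and rose in 1 of 20 cases (10 and 2 adjusted over the list alone, camera adjusted p = 0.0343, and adjusted p = 0.311 with an estimated correlation), with CD44 down 2.07-fold. Basal keratinocyte genes rose in 8 and fell in 5 of 18 cases (8 and 6 adjusted over the list alone, camera adjusted p = 0.0343, and adjusted p = 0.411 with an estimated correlation), with the collagen gene COL7A1 up 4.56-fold. Endothelial markers fell in 3 of 5 cases, also adjusted over the list alone (camera adjusted p = 0.0232, and adjusted p = 0.213 with an estimated correlation), CDH5 among them. Without the first library labelled knockdown the mesenchymal and interferon lists each had an adjusted p of 0.0515, and without the second the basal keratinocyte list had 0.0759. Over 13 alternatives these 3 lists had adjusted p from 0.000165 to 0.311, from 0.00021 to 0.302 and from 0.00144 to 0.411.

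The remaining 17 lists were not called in this contrast. Hypoxia and glycolysis genes divided, with 8 risen and 17 fallen of 32, also adjusted over the list alone (camera adjusted p = 0.0538). VEGFA, which encodes an angiogenic growth factor, rose 4.07-fold to 603 ± 16.0 CPM, and LDHA, a lactate dehydrogenase gene of glycolysis, fell 2.37-fold. Median and mean differed in sign for FOXO targets and PI3K feedback genes (0.02 and -0.24). They also did for apoptosis and autophagy (-0.02 and 0.03) and for Wnt and Notch genes (-0.13 and 0.02). Of 4 tested blood and immune markers 3 fell and 0 rose. Of 4 fibroblast markers 1 fell and 0 rose, and of 6 liver, gut and neural markers 3 fell and 1 rose.

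**Figure D2:**
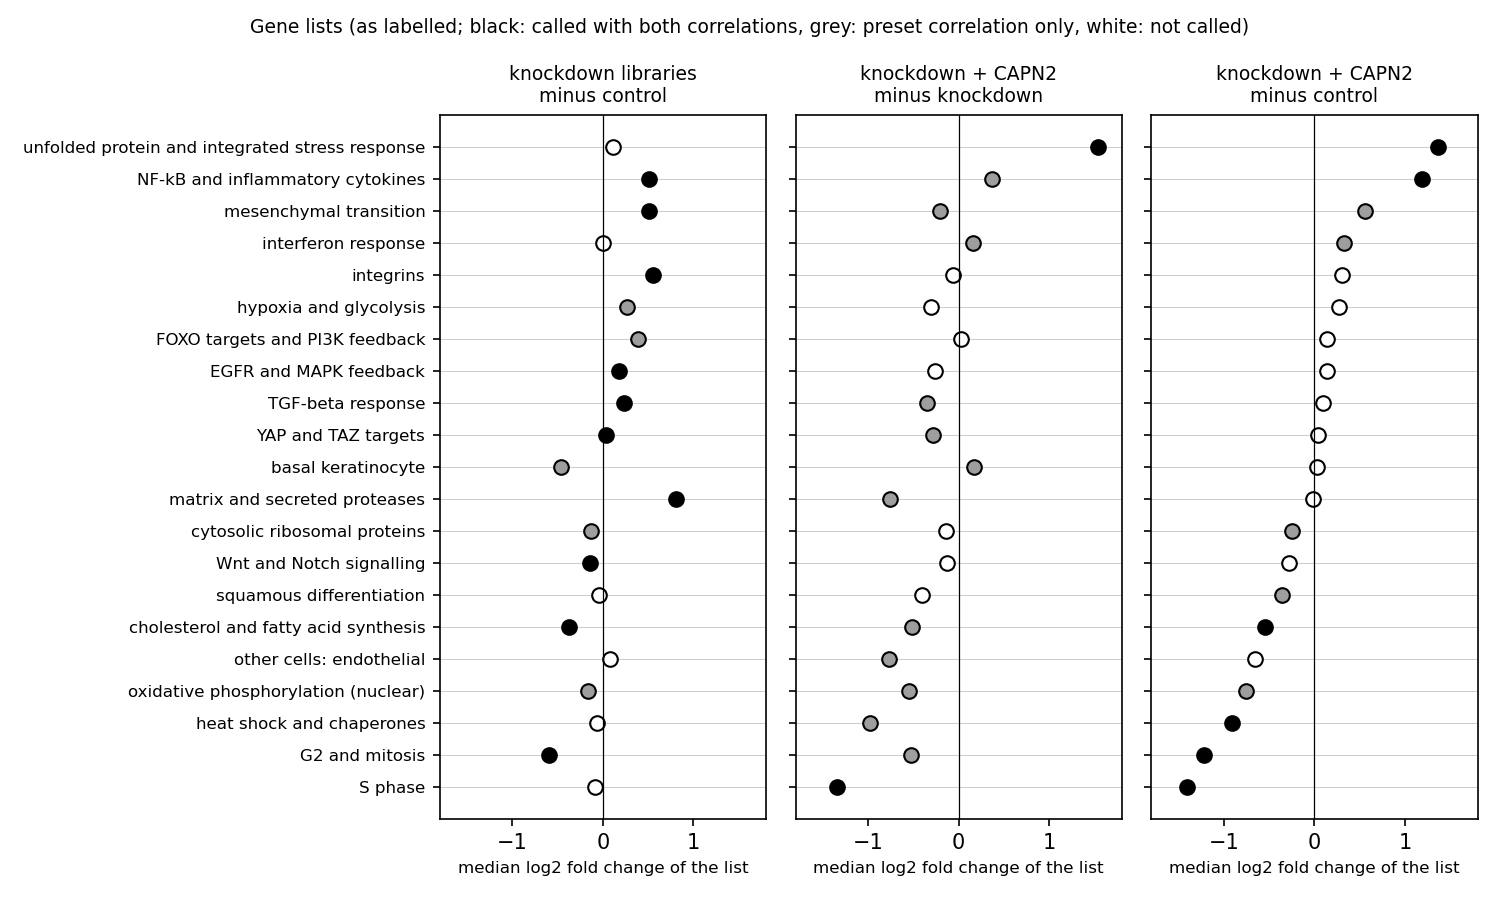
Median log2 fold change of each gene list called in at least 1 contrast, with 1 panel per contrast of the labelled groups and 1 circle per list. Black circles passed camera with the preset and the estimated correlation, grey ones with the preset correlation only and white ones with neither. The unfolded protein list lay at 0.12, 1.54 and 1.36 and the S phase list at -0.08, -1.35 and -1.41 in the 3 panels.

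Against control, the libraries labelled knockdown plus CAPN2 differed in more genes than those labelled knockdown did. HSP90B1, which encodes GRP94, a chaperone of the endoplasmic reticulum, rose 10.2-fold (log2 3.35 ± 0.106 SE) from 483 ± 31.4 to 4917 ± 290 CPM (SD, n = 3), and HSPA5, which encodes BiP, rose 7.74-fold from 672 ± 16.0 to 5205 ± 81.0 CPM. NUCB2 rose 13.7-fold to 164 ± 6.82 CPM. LMNB1 fell 6.35-fold from 376 ± 9.01 to 59.3 ± 0.913 CPM, and MYBL2, a transcription factor gene of the cell cycle, fell 5.70-fold.

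Other large rises were those of DDIT3 (log2 3.71 ± 0.138), ANKRD12 (3.22 ± 0.164), the cholesterol exporter gene ABCA1 (3.19 ± 0.144), CRELD1 (3.19 ± 0.108), ANXA6 (3.17 ± 0.160), SPX (3.10 ± 0.214), the endoplasmic oxidase gene ERO1B (3.09 ± 0.130) and the Golgi gene GOLGB1 (3.07 ± 0.185). Other large falls were those of HSPA6 (-3.90 ± 0.210), TXNIP (-3.35 ± 0.110), E2F2 (-3.08 ± 0.179), MRPL12 (-2.87 ± 0.370), SAC3D1 (-2.65 ± 0.204), AKR1B10 (-2.61 ± 0.292), ZNF488 (-2.59 ± 0.129) and FEN1 (-2.42 ± 0.107). For these 20 genes edgeR's adjusted p lay between 4.46e-14 for NUCB2 and 0.00018 for MRPL12. Of 16812 genes, 9468 were called, 4692 higher and 4776 lower, with 1951 higher and 1260 lower by at least 2-fold. The share of higher calls was 49.6% and became 57.9% with upper-quartile factors. The groups' libraries did not overlap for 66.9% of genes, against 10% by chance.

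Of the unfolded protein and integrated stress response list, 28 of 31 genes rose and 0 fell, also adjusted over the list alone (median log2 1.36, camera adjusted p = 8.24e-40, and adjusted p = 0.00254 with an estimated correlation). NF-kB and cytokine genes rose in 23 of 30 cases and fell in 2 (25 and 3 adjusted over the list alone, median 1.18, camera adjusted p = 2.33e-11, and adjusted p = 0.0337 with an estimated correlation), with the chemokine genes CXCL2 and CCL20 up 7.40-fold and 7.21-fold. S phase genes fell in 31 of 33 cases and rose in 0, also adjusted over the list alone (median -1.41, camera adjusted p = 1.8e-35, and adjusted p = 0.00254 with an estimated correlation), with the helicase gene MCM4 down 3.10-fold from 739 ± 12.1 to 239 ± 1.60 CPM. G2 and mitosis genes fell in 27 and rose in 2 of 34 cases, also adjusted over the list alone (median -1.22, camera adjusted p = 1.61e-18, and adjusted p = 0.018 with an estimated correlation). CDC20 fell from 450 ± 20.6 to 113 ± 7.31 CPM, and the 2 that rose were CENPE, 4.94-fold, and CENPF, 2.27-fold. Heat shock genes fell in 13 and rose in 1 of 14 cases, also adjusted over the list alone (median -0.91, camera adjusted p = 1.13e-09, and adjusted p = 0.0357 with an estimated correlation), with HSPE1, whose exons overlap those of HSPD1, down 3.75-fold. The 1 that rose, HSPA4L, was 1.38-fold higher, and its log2 fold change was -0.10 after the GC and length correction. Cholesterol and fatty acid synthesis genes fell in 23 and rose in 3 of 31 cases (24 and 3 adjusted over the list alone, median -0.55, camera adjusted p = 1.74e-07, and adjusted p = 0.0159 with an estimated correlation), with DHCR7 down 3.07-fold.

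Another 5 lists passed with the preset correlation only. Nuclear oxidative phosphorylation genes fell in 39 and rose in 0 of 42 cases, also adjusted over the list alone (camera adjusted p = 1.71e-11, and adjusted p = 0.303 with an estimated correlation), with COX8A down 2.42-fold. Cytosolic ribosomal protein genes fell in 37 and rose in 2 of 74 cases, also adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.787 with an estimated correlation). Mesenchymal genes rose in 12 and fell in 5 of 20 cases, also adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.303 with an estimated correlation), with the matrix gene TNC up 3.19-fold. Interferon response genes rose in 22 and fell in 10 of 39 cases (22 and 11 adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.303 with an estimated correlation), with SAMD9L up 4.15-fold. Squamous differentiation genes fell in 10 and rose in 2 of 25 cases, also adjusted over the list alone (camera adjusted p = 0.043, and adjusted p = 0.523 with an estimated correlation), with KRT13 down 3.70-fold. That call was also lost without the first or the third library labelled knockdown (adjusted p = 0.056 and 0.0559) and without the first labelled knockdown plus CAPN2 (0.0518). It and the call of the ribosomal list were lost after the GC and length correction (adjusted p = 0.374 and 0.348), within 0.00171 to 0.523 and 0.00191 to 0.787 over 13 alternatives.

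The remaining 20 lists were not called against control. Replication histone genes, a list for RNA quality, fell in 6 and rose in 0 of 13 cases, also adjusted over the list alone (median -0.60, camera adjusted p = 0.169, and adjusted p = 0.000569 with fry). Of marker genes of other cells, 3 of 5 endothelial and 3 of 4 blood genes fell and 0 rose. Of 4 fibroblast markers 2 fell and 1 rose, and of 6 liver, gut and neural markers 3 fell and 1 rose. Protease genes rose in 12 and fell in 5 of 28 cases (12 and 6 adjusted over the list alone, camera adjusted p = 0.0779), and their median of -0.02 and mean of 0.34 differed in sign. The same held for the lists of epithelial junction genes (0.05 and -0.07), of basal keratinocyte genes (0.03 and -0.06) and of apoptosis and autophagy (-0.02 and 0.25). CAPN1 was 1.79-fold lower than in control, where it stood at 473 ± 19.8 CPM. CAPN5, at only 1.40 ± 0.328 CPM in control, was 2.12-fold higher. The calpain list was not called (camera adjusted p = 0.92).

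Whether changes found in the libraries labelled knockdown were turned back in those labelled knockdown plus CAPN2 was asked here with the third group. MMP1 rose from 64.3 CPM in control to 442 CPM and stood at 62.1 CPM in the libraries labelled knockdown plus CAPN2, where its log2 fold change against control was -0.05 ± 0.093 (SE, edgeR adjusted p = 0.664). MMP10 went from 21.2 to 163 and 18.1 CPM, MMP3 from 1.68 to 44.4 and 4.02 CPM, SYTL2 from 0.728 to 14.3 and 1.15 CPM, and DIO2 from 1.20 to 22.2 and 2.98 CPM. In the other direction MBNL3, which encodes a splicing regulator, went from 41.1 to 12.7 and 43.2 CPM and SH3PXD2B from 10.0 to 3.27 and 10.1 CPM. NUPR1, SLC6A9 and ALDH1L2 went past control, to log2 fold changes of 2.38 ± 0.242, 1.05 ± 0.135 and 1.85 ± 0.119 against it.

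Of the 5812 genes called in the libraries labelled knockdown, 1850 were called in the opposite direction in the next contrast and 1578 in the same direction. Those moved back were 959 of 2696 risen genes (35.6%) and 891 of 3116 fallen genes (28.6%). Of the risen genes 593 moved further, fewer than moved back, and of the fallen genes 985 did, more than moved back. Of the 959, 598 were not called against control in the end, and 187 were called on its opposite side. Of the 891, these were 542 and 267. Independent lists of these sizes would share 1427 genes in opposite and 1435 in the same direction. Simulated data without any effect gave at most 1 gene in the opposite direction, which sets no scale for the 1850, since a gene counts only if it is called in both contrasts. Across genes the 2 sets of fold changes had a covariance of -0.133, against -0.0334 in 20 simulated data sets (range -0.0349 to -0.0318), a difference of -0.099, and Pearson's r was -0.268 against -0.492. All simulated data took 1 spread per gene from all 9 libraries, although those labelled knockdown were the least alike. The simulated covariance may therefore be understated and the simulated ranges too narrow. The libraries labelled knockdown enter both contrasts. With 1 of them used for one contrast and the others for the second, in 6 arrangements, the covariance was -0.149 to -0.05 (-0.0034 to 0.0038 in simulated data without effect), and 951 to 1573 genes moved in the opposite and 742 to 2121 in the same direction. With library 1, 2 or 3 labelled knockdown alone in the first contrast, 951, 1278 and 1573 genes moved in the opposite direction, against 655, 1372 and 999 expected of independent lists. With each alone in the second contrast the numbers were 1297, 1423 and 1410, against 1198, 840 and 1279. The opposite direction held more genes than the same direction in 3 of the 6 arrangements and fewer in the others, as in 1278 against 2121 with library 2 alone in the first contrast.

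Among the lists, protease genes moved back in 14 of 19 called cases and Wnt and Notch genes in 12 of 16. In Fisher's exact test among the 5812 genes their adjusted p was 0.00666 and 0.0075, and the other 29 of 31 lists did not pass. The unfolded protein list moved back in 14 of 27 cases (Fisher's exact test, adjusted p = 0.115). That test treats the genes of a list as independent, and the libraries labelled knockdown enter both contrasts, so its p-values may be too small. As a whole list, Wnt and Notch genes were not called in the second contrast (10 risen, 11 fallen, camera adjusted p = 0.931). Protease genes passed there with the preset correlation only. The set that stood apart from both others in the same direction most often was the one labelled knockdown plus CAPN2, in 5992 genes, followed by control in 3756 and the libraries labelled knockdown in 1850.

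**Figure D3:**
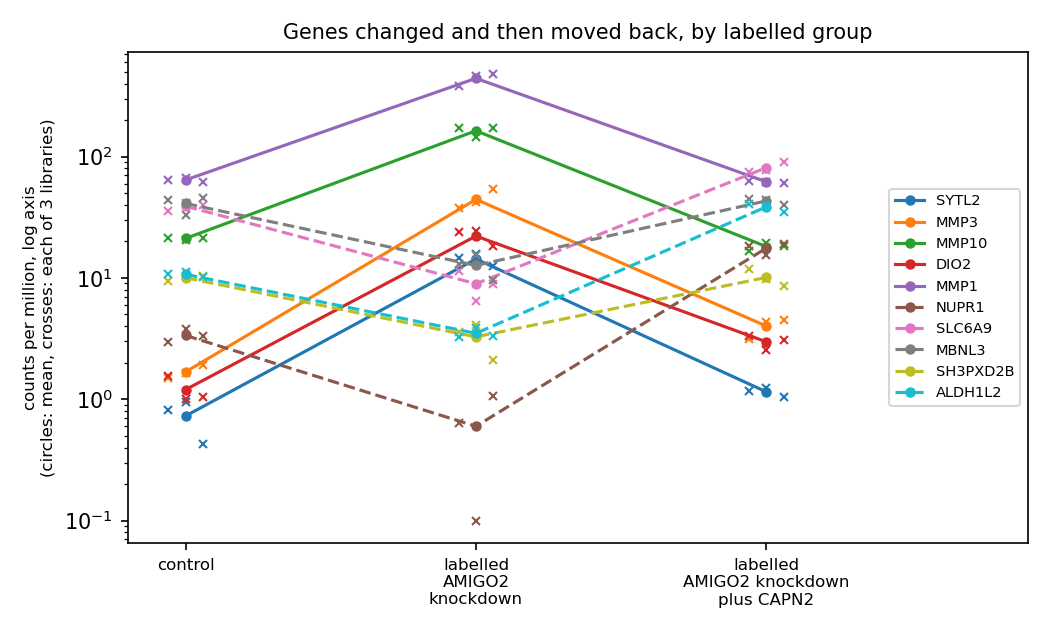
Levels in CPM on a log axis of the 10 named genes that moved back, with a circle for the mean and crosses for the 3 libraries of each labelled group. Solid lines join the means of genes that rose and then fell, such as MMP1 at 64.3, 442 and 62.1, and dashed lines those that fell and then rose, such as MBNL3 at 41.1, 12.7 and 43.2.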

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

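The GC and length correction and the comparison without shared libraries were chosen after the data were seen. Requiring a 2-fold change left 1111, 2271 and 3211 of the 5812, 8278 and 9468 changed genes, by construction. Under all other settings these counts, and the 1850 genes moved back, stayed within 1.5 times, except that 951 moved back with no shared library and the first knockdown library alone in the first contrast (1278 to 1573 in the other 5 arrangements). Leaving out each library gave 4288 to 6427, 7071 to 8478, 8317 to 9950 and 1464 to 2299 genes. AMIGO2 between the libraries labelled knockdown and control stayed near 0, at -0.062 to 0.09 without each library, changing sign without control 2 (-0.033), control 3 (-0.004) and knockdown 2 (-0.062), and was -0.087 after the GC and length correction. That correction gave CAPN2 at -0.223 in the same contrast, now past the threshold (adjusted p = 0.00938, range 0.00938 to 0.491), and at -0.057 between knockdown plus CAPN2 and control, a change of sign. The last passed with upper-quartile factors (0.213) and in the fit to the 2 groups alone (0.12). CAPN2 between the labelled perturbed sets no longer passed without a filter (0.218), and ran from 0.206 to 0.275 without each library. The causes were not tested. An estimated correlation called 10, 2 and 6 lists and fry 20, 26 and 23, in place of 15, 14 and 11. Fry does not compare a list with other genes. Of the 40 list calls, 22 were lost with an estimated correlation, 3 with fry, 4 with the GC and length correction and 7 on leaving out some library. No list test turned in direction, but the median of YAP and TAZ targets between knockdown and control (0.036) turned below 0 without knockdown 2 (-0.012) and with the GC and length correction. HSPA4L against control turned to -0.096 with the GC and length correction. Upper-quartile factors moved the median of all genes by 0.103 in knockdown plus CAPN2 against control, and none of the 40 called lists changed the sign of its median under 4 scalings or tools. Replicate numbers did not pair the libraries: 0 of 9 same-number pairs correlated above 0.1 (-0.111 to 0.063), and 1 of 9 libraries correlated best with its own number. The replicate block gave 5376, 7912 and 9149 genes and 1670 moved back. Fits to the compared groups alone gave 5068, 7620 and 10348 genes and 1548 moved back. These are fewer than in the main fit for both contrasts with the libraries labelled knockdown and more for the contrast without them. In simulated data with 200 changed genes, 53.7%, 47.8% and 61.2% of 1.5-fold changes were called, and depth was not varied by itself. Far more genes were called in the data, which makes the adjusted threshold less strict there. These shares therefore do not measure the sensitivity in the 3 contrasts.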

Other observations

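The tests of why AMIGO2 was no lower and CAPN2 little higher, the comparison without shared libraries, and the division of the stress response list into arms were chosen after those results were seen. The 2 further lists that tested the division were written before their values were seen.

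The divided stress response list of the libraries labelled knockdown held ER chaperones that rose and genes of amino acid supply that fell. A hypothesis is that these libraries had a higher ER chaperone response with a lower amino acid response. It was tested on 2 lists of further genes, none of them on the earlier lists. The libraries were the same ones that raised the hypothesis. The lists therefore show whether the pattern extends to further genes, not whether it would recur in other cultures. Of 30 further amino acid response genes, 20 fell and 1 rose in the libraries labelled knockdown against control (median log2 -0.36, camera adjusted p = 1.74e-06, and adjusted p = 0.0152 with an estimated correlation). Those that fell included the aminoacyl-tRNA synthetase gene AARS (-0.62 ± 0.088 SE) and the transporter gene SLC7A5 (-0.61 ± 0.089), and the 1 that rose was SLC38A2 (0.72, edgeR adjusted p = 2.3e-05). Of 39 further ER chaperone and secretion genes, 17 rose and 4 fell (median 0.22, camera adjusted p = 0.000351), with calreticulin, CALR, at 1.08 ± 0.091. The ER call was lost at adjusted p = 0.0717 with an estimated correlation, and its median shrank to 0.07 after the GC and length correction (adjusted p = 0.00953). The medians of both lists differed by 0.585, and by 0.381 after that correction, where the amino acid median was -0.31, in the direction the hypothesis needs, with the ER part the less certain one. In the libraries labelled knockdown plus CAPN2 against those labelled knockdown both lists were higher, with medians of 0.89 (adjusted p = 7.53e-19) and 0.42 (adjusted p = 1.8e-07), and with adjusted p = 0.000725 and 0.0181 with an estimated correlation. AARS, SLC7A5, SLC38A2 and CALR were named after their values were seen.

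TXNIP fell in the libraries labelled knockdown plus CAPN2 together with ARRDC4, a related arrestin-domain gene that is known to share its glucose-dependent regulation and was looked up after TXNIP was seen. ARRDC4 stood at 12.5 ± 1.07 CPM in control, 27.2 ± 0.773 CPM under the knockdown label and 4.34 ± 0.542 CPM under the label of knockdown plus CAPN2 (SD, n = 3). Its log2 fold change was 1.12 ± 0.123 (SE) in the contrast of knockdown with control and -2.65 ± 0.137 in the next (edgeR adjusted p = 1.42e-06 and 2.77e-11).

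AMIGO2 was no lower in the libraries labelled knockdown, and CAPN2 was little higher under the label of overexpression. A single mislabelled library among the knockdown libraries is argued against, because the lowest of the 3 still held AMIGO2 at 88.7% of the control mean, and too few counts are not the limit, as the lower 95% bound of the AMIGO2 log2 fold change was -0.235. Exchanged group labels stay open, since 0 of the 6 ways of giving the 3 labels to the 3 sets moved both genes by at least 0.5 log2 as named, but no 2 sets differed by that much in CAPN2, so the values already seen fixed this count. With the set labelled knockdown plus CAPN2 as control, AMIGO2 would be lower by 0.49 and 0.50 log2 in the others, while CAPN2 would be lower in them as well. A knockdown that acts on the protein alone, a loss of the constructs before harvest, and counts for another experiment stay open too, since protein and construct sequence were not analysed here.

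Stress response genes were higher and S phase genes lower in the libraries labelled knockdown plus CAPN2. A bias of GC content and gene length is argued against as the whole cause, since after the correction the smaller of the 2 list medians kept 99.4% of its value and both lists stayed past the threshold. Full replacement by a line with other expressed genes is argued against. This is because 0 genes were without counts in all 3 libraries of one group and at 5 CPM or more in every library of the other. A partial admixture or a similar line could give the same count and stays open, since sequence variants were not examined. The labelled manipulation and a difference in culture conditions, which the labels do not record, may each account for the pattern, and neither was tested.

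Genes that fell in the libraries labelled knockdown moved further (985) more often than back (891) in those labelled knockdown plus CAPN2. Still, of all genes changed in the former, many moved back in the latter. Noise of the shared libraries is argued against as the whole cause of the observed covariance of -0.133. With no library in both contrasts the covariance was still -0.149 to -0.05, below simulated data without effect (lowest -0.0034) in all 6 arrangements. The shared libraries may still add to it. In 3 arrangements more genes moved further than back. The simulated data hold no difference between sets. A real difference of the libraries labelled knockdown from both other sets would also give a negative covariance. The covariance therefore does not show a turning back by the labelled CAPN2. Of 100 drawn splits of the 9 libraries, 2 gave at least 1850 genes, the real one included. The other of these 2 gave 4680 genes with the libraries labelled knockdown plus CAPN2 as its middle set, and the next highest gave 1150. Drawn splits other than the real one mix libraries of different groups, which widens the spread within sets. They are not data without effect, so the draw excludes no chance and does not show that genes turned back. None of the drawn splits had the same 3 sets in other roles, and with control or the libraries labelled knockdown plus CAPN2 as the middle set the count was 3756 or 5992, so the real 1850 was the lowest of the 3 and a turning back by the labelled CAPN2 stays open.

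Splits of the 6 libraries of each contrast were too few for a share under 0.05, at 10 each. In each contrast 1 of 10 splits, the real one, gave as many changed genes, with 5812, 8278 and 9468 genes against 0 in the highest other split by edgeR. At an unadjusted p under 0.05 the other splits gave up to 915, 1369 and 210 genes. For called lists 1 of 10 splits reached the real value too. The contrasts had 15, 14 and 11 lists, against 10, 9 and 10 in the highest other split. Every other split mixes libraries of both groups, which widens the spread within sets and keeps part of the group difference. Such splits are not data without effect, so neither their 0 changed genes nor their called lists set a scale.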
